A study of Homo sapiens with 9 samples.

How the data were processed

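RNA-seq was analysed for 9 libraries of KYSE150 cells, an established human cell line of esophageal squamous cell carcinoma. Per the labels, the libraries fell into 3 groups of 3, named FadA, 0M and NC. The FadA group had been exposed to 60 µg/ml of FadA, a protein of the bacterium Fusobacterium nucleatum, for 2 days (48 hours). The labels give the treatment of both 0M and NC as control, and they do not say which of these groups received the phosphate-buffered saline that the treatment protocol names. The same labels give 1 batch for all libraries, so no split by batch could be made. What the letters 0M and NC stand for is not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

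Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit. Per the submitters' processing notes, HISAT2 was used and the genome build was GRCh38; the version of HISAT2, the program that assembled and counted transcripts, the annotation and the use of strand are not given in the sources used here. The authors deposited an expected count, that is an estimated count already rounded to a whole number, for each of 21749 gene entries and 111589 transcripts in each library. The authors also deposited an FPKM and a TPM value for each entry. Between any library and FadA 1, the ratio of count to FPKM differed by nearly the same factor for all transcripts with more than 500 counts, the SD of its log2 over transcripts being at most 0.000587. The gene count equalled the sum of its transcripts for 20423 of 20423 named genes compared. The entries comprised 20422 with an Ensembl gene identifier and 1326 assembled transcripts with no gene, which held between 0.594% and 0.860% of the counts of a library and were kept in the library sizes and tests. The 13 mitochondrially encoded genes were listed, and 0 of them had a count in any library, so the list of these genes was not tested.

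The tests had been planned for read counts; because the unit is an expected count, the whole numbers as deposited were used in the same tests. All calculations used R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 14078 genes, and libraries were scaled by TMM (trimmed mean of M values). Differences were tested with edgeR's quasi-likelihood test with 1 coefficient per group, fitted to all 9 libraries so that the groups shared an estimate of the spread with 6 residual degrees of freedom. The contrasts were FadA minus the mean of both controls, FadA minus 0M, FadA minus NC and NC minus 0M. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 changes are given with their standard error (SE), group levels in CPM (counts relative to the library total, scaled by TMM) with their SD. Counts in these libraries carry no molecular identifiers, so floors taken from them cover counting error only.

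The groups, the contrasts, the tests, the rule for named genes, 34 gene lists and all other settings except those named below as added were chosen before the data were examined. The rule took named protein-coding genes with a mean of at least 5 CPM. It named TFRC whatever its result. For FadA against both controls it named the 10 largest rises and the 10 largest falls among genes under the adjusted threshold whose 3 FadA libraries lay all above or all below the 6 control libraries, and for the other contrasts the 5 largest rises and falls without overlap, or the 5 smallest p-values if no gene passed. For each list it named up to 4 members with the smallest p-value, and members above 1000 CPM. Genes named outside this rule are said to be so.

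The lists covered metabolic, stress, immune, cell-cycle, epithelial and signalling genes and markers of cell types other than epithelium. Of the lists, 33 had at least 5 tested members and were tested with camera of limma 3.58.1, which asks whether the genes of a list lie higher or lower than the other genes. A preset correlation between genes of 0.01 was used, with Benjamini-Hochberg adjustment over the 33 lists, and the test was repeated with a correlation estimated from the data. For each list, genes were also counted with p-values adjusted over the list alone. Positions and overlaps of genes came from GENCODE v29 on GRCh38, which held 13141 of the 14078 tested genes by identifier. Since the use of strand is not stated, genes that overlap another gene are named as uncertain.

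Depth ranged from 23373732 to 31427953 counts per library. The procedure was tested on simulated data in which known sets of genes were altered, with 13904 genes in the fit. For FadA against both controls, 43.3%, 74.6% and 89.4% of the genes altered by 0.5, 1 and 2 on the log2 scale were called, and 0.0432% of the unaltered genes. For FadA against 0M these shares were 32.8%, 68.7%, 83.3% and 0.0288%, and for FadA against NC 34.3%, 70.1%, 87.9% and 0.0504%. For NC against 0M, where no gene had been altered, the share called was 0%. A list shifted by 0.5 on the log2 scale in 13916 simulated genes had a camera adjusted p of 7.3e-84 after Benjamini-Hochberg adjustment, and 0 of 32 unshifted lists were called. Simulated genes were drawn independently of each other, whereas in the data the estimated correlation of the cholesterol list was 0.682. The simulation therefore does not show how often camera calls unshifted lists of correlated genes.

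The other settings tried were the DESeq2 1.42.0 Wald test, DESeq2 size factors and upper-quartile factors within edgeR, no filter beyond 1 count in total, a filter of 1 CPM in 3 libraries, an adjusted threshold of 0.01, an absolute log2 change of at least 1, limma-trend on the deposited TPM with a pseudocount of 1 or 0.1, limma voom with sample weights, the replicate number as a block, fits with only the compared groups, the 6 controls as a single group, fry in place of camera, and each library left out in turn. After seeing the data, offsets that remove each library's trend with GC content and transcript length (loess span 0.4) were added; they used GENCODE v29 transcripts and covered 13109 of the tested genes (93.1%). The list tests without each library were read for NC replicate 3 and FadA replicate 1 in particular, also after seeing the data. The share of other choices of libraries that gave as large a result was counted for each comparison. Values of 1 gene that the rule for named genes would have included are not reported here.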

Results

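Transcript levels were measured in KYSE150 cells, an established human line of squamous cell carcinoma of the esophagus, with and without exposure to FadA. FadA is an adhesin of Fusobacterium nucleatum, a bacterium of the mouth that is also found in tumours. The 9 libraries formed a FadA group (60 µg/ml for 2 days) and the control groups 0M and NC, each with n = 3, and libraries are named here by group and replicate number. Total counts were 31427953, 26350039 and 23408059 in FadA 1, 2 and 3, 24399022, 24365374 and 26763284 in 0M 1, 2 and 3, and 23373732, 24431945 and 26985536 in NC 1, 2 and 3. Between 15241 and 15695 genes had a count in each library, and 14078 were tested. Every pair of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom from 8.03 to 54.3. No library was therefore taken for another one of its group deposited again. Pairs across groups were not compared in this way.

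Libraries of a group did not lie equally close together. The highest values of chi-square per degree of freedom were those of NC 3 with NC 1 (49.2) and NC 2 (54.3), followed by FadA 1 with FadA 2 (20.4) and FadA 3 (24.9). On the first principal component of log2 CPM, which held 24.97% of the variance, NC 3 lay at 21.9. The FadA libraries lay at 48.8, 25.8 and 32.97, the 0M libraries between -23.3 and -16.5, and NC 1 and NC 2 at -28.5 and -44.1.

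**Figure D1:**
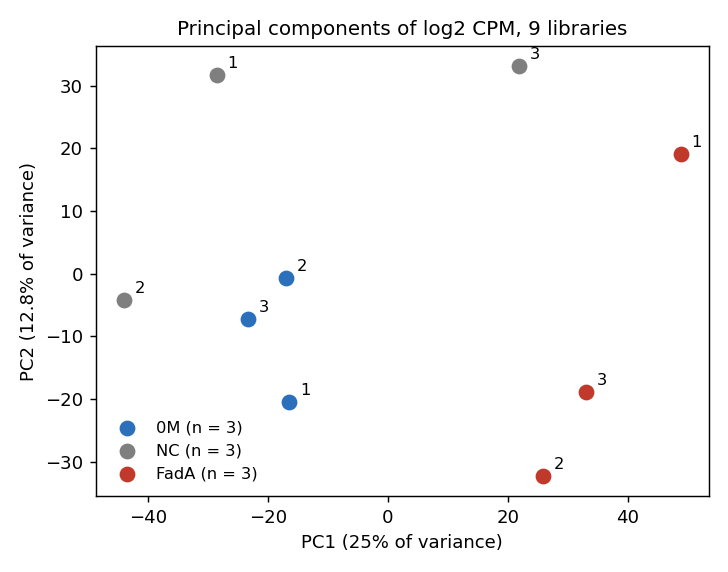
Positions of the 9 libraries on the first and second principal components of log2 CPM (24.97% and 12.8% of the variance; axes in component units), each point a library with its replicate number, coloured by group. NC 3 lies on the side of the FadA libraries on the first component, at 21.9.

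The series title names TFRC as the protein that FadA binds, and its transcript was therefore compared first. TFRC, the transferrin receptor that brings iron into cells, rose 1.48-fold with FadA. Its level was 1452 ± 30.2 CPM in FadA (SD, n = 3), 961 ± 35.8 CPM in 0M and 999 ± 16.6 CPM in NC. The 3 FadA libraries lay between 1434 and 1487 CPM, above all 6 control libraries, which lay between 920 and 1017 CPM. TFRC (ENSG00000072274) is encoded on the minus strand of chromosome 3 at positions 196027183 to 196082189 of GRCh38, and no other protein-coding gene overlaps it in GENCODE v29. The log2 change was 0.57 ± 0.04 (SE) against both controls, with an adjusted p of 0.000566 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Against 0M alone it was 0.60 ± 0.04 and against NC alone 0.54 ± 0.04, with adjusted p of 0.0016 and 0.00136 in the same edgeR test after Benjamini-Hochberg adjustment.

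Of 18 tested genes of iron uptake, storage and export, 2 rose and 2 fell, and the same numbers passed when adjusted over the list alone. Besides TFRC, ACO1, a cytosolic aconitase that without its iron-sulphur cluster binds iron-responsive transcripts, rose by 0.33 ± 0.09 on the log2 scale. LRP1, an endocytic receptor whose ligands include haem-bound hemopexin, had a log2 change of -0.70 ± 0.16 and overlaps STAT6 on the other strand. The other gene that fell was LCN2, which encodes the siderophore-binding protein lipocalin, at -1.20 ± 0.31; it lay below the level set for named genes and was named after its values were seen. FTH1, the ferritin heavy chain, stood at 2204 ± 397 CPM in FadA against 1450 ± 39.1 in 0M and 1703 ± 686 in NC and did not pass, with an adjusted p of 0.115 in edgeR after Benjamini-Hochberg adjustment; it overlaps BEST1 on the other strand. The list as a whole did not pass the camera test, with an adjusted p of 0.424 after Benjamini-Hochberg adjustment. Only 1 member rose when FadA 1, FadA 2, FadA 3, 0M 1, 0M 2, 0M 3 or NC 1 was left out; without NC 3, 6 rose and 4 fell. The number that fell was 0 without FadA 2 and 1 without FadA 1 or any control library other than NC 3.

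Exposure to FadA was next compared with the mean of both control groups over all genes. Of 14078 genes, 1374 were higher and 1241 lower in FadA, and 28 rose and 231 fell by at least 2-fold. Among the named genes with the largest rises were MYH15, a myosin heavy chain (log2 change 1.58 ± 0.31), OSBP2, an oxysterol-binding protein (1.32 ± 0.17), and METRNL, a secreted protein (1.28 ± 0.22). SERPINB2, an inhibitor of plasminogen activators, rose by 1.26 ± 0.21, and GRHL1, an epithelial transcription factor, by 1.20 ± 0.17. TGM2, the transglutaminase that cross-links proteins, rose from 288 ± 12.5 CPM in 0M and 260 ± 41.7 CPM in NC to 578 ± 70.3 CPM in FadA (SD, n = 3 each), a log2 change of 1.08 ± 0.10. The other named rises were IGFN1 (1.41 ± 0.25), MARCHF4, a membrane ubiquitin ligase (1.20 ± 0.25), SLC30A1, a zinc exporter (1.14 ± 0.20), and MT1E, a metal-binding metallothionein (1.08 ± 0.27).

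The largest named fall was that of LOXL4, a lysyl oxidase that cross-links collagen, from 8.32 and 10.8 CPM in 0M and NC to 2.36 CPM in FadA, a log2 change of -2.00 ± 0.16. DNAH1, a dynein of cilia (-1.80 ± 0.35), CLEC2B, a C-type lectin (-1.77 ± 0.27), SLITRK6, a neuronal-type membrane protein (-1.64 ± 0.21), and ACP3, an acid phosphatase (-1.64 ± 0.32), followed. LTBP2, a protein of extracellular microfibrils (-1.62 ± 0.29), TMPRSS4, a membrane serine protease (-1.57 ± 0.26), and ZNF117, a zinc-finger protein (-1.56 ± 0.29), also fell. HCAR2, a receptor for hydroxycarboxylic acids, changed by -1.54 ± 0.20 and SYNE1, a protein of the nuclear envelope, by -1.54 ± 0.13. Counts of MT1E and HCAR2 are uncertain because near-identical paralogs may share their reads, and those of SERPINB2, TGM2, TMPRSS4, ZNF117 and SYNE1 because they overlap SERPINB10, RPRD1B, SMIM35, ERV3-1 and ESR1.

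Adjusted p-values of these genes ran from 0.00115 for LOXL4 to 0.0264 for MT1E in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 2615 genes (18.6%) passed, with a median absolute log2 change of 0.37. The FadA libraries lay entirely above or below the controls for 3098 tested genes (22.01%, chance 2.38%) and for 2258 of those that passed. Chance here treats the libraries as interchangeable, and shifts of a whole library can move such shares far from it. Single libraries lay outside the range of the other 8 in 9.03% to 45.8% of 8738 genes, where chance gives 22.2%. The same limit holds for the shares without overlap in the contrasts below. Without FadA 1, MYH15, MARCHF4 and MT1E no longer passed, with adjusted p of 0.0583, 0.0638 and 0.121 in edgeR after Benjamini-Hochberg adjustment, against 0.00138 to 0.0409, 0.000468 to 0.0414 and 0.00185 to 0.0619 without each other library. MT1E also did not pass without 0M 1, 0M 2, 0M 3, NC 1 or NC 2 (0.0529, 0.0568, 0.0619, 0.0521 and 0.0511, edgeR with Benjamini-Hochberg adjustment). The number of genes was 1123 without FadA 1, 931 without FadA 2, 1498 without FadA 3, 1434 without 0M 2 and 1404 without 0M 3, and it was 1485 without 0M 1, 1747 without NC 1, 1729 without NC 2 and 5513 without NC 3. With upper-quartile factors 1039 genes were higher and 1504 lower, and with limma-trend on log2(TPM + 1) 643 were higher and 1378 lower.

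Gene lists were compared in the same contrast, and 12 of the 33 tested passed the camera test after Benjamini-Hochberg adjustment. With a correlation between genes estimated from the data, 0 lists passed camera after adjustment and 1 had an unadjusted p under 0.05, while fry, which asks whether the genes of a list move on balance in 1 direction, called 13. Of all 84 choices of 3 libraries against the other 6, 26 gave at least 12 lists, the real one included, and the highest other choice gave 18.

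Cholesterol genes formed the list with the smallest p-value. Of 23 tested genes of cholesterol synthesis and uptake, 18 fell and 5 did not pass, and 19 fell when adjusted over the list alone. INSIG1, which holds the sterol sensor of the cell in the endoplasmic reticulum, fell from 296 ± 6.26 CPM in 0M and 270 ± 88.0 CPM in NC to 113 ± 9.94 CPM in FadA (SD, n = 3 each), a log2 change of -1.32 ± 0.19. SQLE, the squalene epoxidase, changed by -0.99 ± 0.15, HSD17B7, a later enzyme of the pathway, by -0.70 ± 0.08, and TM7SF2, a sterol reductase whose gene overlaps VPS51, by -0.65 ± 0.08. The median log2 change of the list was -0.54. The camera adjusted p was 4.56e-16 with Benjamini-Hochberg adjustment, and the adjusted p = 0.522 with an estimated correlation. Relative to the 0M mean, the list mean was -0.70, -0.61 and -0.59 in FadA 1, 2 and 3 and -0.44 in NC 3, and it lay between -0.05 and 0.11 in the other controls. The number of genes that fell was 9 without FadA 1, 10 without FadA 2, 12 without FadA 3 and 20 without NC 3.

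Of 35 tested interferon-stimulated genes, 9 fell and 26 did not pass, and 15 fell when adjusted over the list alone; the median log2 change was -0.61. SAMD9, a restriction factor of poxviruses, changed by -0.49 ± 0.07, PARP14, a mono-ADP-ribosyltransferase, by -0.49 ± 0.12, HERC6, a ubiquitin ligase family member, by -0.67 ± 0.18, and IFIH1, a sensor of double-stranded RNA, by -0.48 ± 0.13. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 2.63e-06, and the adjusted p = 0.615 with an estimated correlation. The number that fell was 2 without FadA 1, 2 without FadA 2, 6 without FadA 3, 3 without each 0M library or NC 2, 4 without NC 1 and 21 without NC 3. The list mean was -0.48 in NC 3, and -0.84, -0.41 and -0.51 in FadA 1, 2 and 3, relative to 0M.

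Of 19 tested genes of MHC class I and antigen processing, 3 fell over all genes, and 8 fell and 1 rose when adjusted over the list alone. Among those that fell over all genes were PSMB10, a subunit of the immunoproteasome (-0.67 ± 0.15), and HLA-C (-0.52 ± 0.15), whose reads may be shared with near-identical genes. In the camera test, the Benjamini-Hochberg adjusted p was 0.0197, and the adjusted p = 0.639 with an estimated correlation; without FadA 1 the camera adjusted p was 0.175, and without the other libraries it ran from 1.4e-05 to 0.0492. The number that fell was 0 without FadA 1, 1 without FadA 2, FadA 3 or any 0M library, 2 without NC 1 or NC 2, and 12 without NC 3. Relative to 0M, the list mean was -0.30 in NC 3 and -0.41, -0.20 and -0.14 in FadA 1, 2 and 3.

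Of 16 tested genes of basal squamous identity, which mark the dividing layer of squamous epithelium and its anchorage, 9 fell, 1 rose and 6 did not pass, and 13 fell and 1 rose when adjusted over the list alone. KRT5, the basal keratin, changed by -0.26 ± 0.04 and stood at 1348 ± 46.6 CPM in FadA against 1762 ± 4.23 in 0M and 1470 ± 75.5 in NC (SD, n = 3 each). PERP, a desmosomal protein, changed by -0.52 ± 0.06, DST, a linker of hemidesmosomes, by -0.54 ± 0.08, and NGFR, a neurotrophin receptor, by -1.21 ± 0.18. BNC1, a zinc-finger protein of basal keratinocytes named after its values were seen, rose by 0.25 ± 0.06. The camera adjusted p was 4.07e-07 with Benjamini-Hochberg adjustment, and the adjusted p = 0.522 with an estimated correlation. The number that fell was 5 without FadA 1, 4 without FadA 2 and 6 without 0M 1 or 0M 2, and BNC1 did not pass without FadA 1, FadA 2 or any 0M library. The list mean was -0.37 in NC 3 and -0.61, -0.43 and -0.37 in FadA 1, 2 and 3, relative to 0M.

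Of 18 tested cytosolic heat-shock genes, 7 rose, and 8 rose when adjusted over the list alone. HSP90AA1, the inducible HSP90, rose from 1648 ± 9.47 CPM in 0M and 1596 ± 183 CPM in NC to 2385 ± 55.8 CPM in FadA (SD, n = 3 each), a log2 change of 0.56 ± 0.06; it overlaps WDR20 on the other strand. HSPH1, a large heat-shock protein, rose by 0.32 ± 0.04, STIP1, a co-chaperone, by 0.36 ± 0.04 and HSP90AB1, the constitutive HSP90, by 0.32 ± 0.05. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.000271, and the adjusted p = 0.522 with an estimated correlation. Relative to 0M, the list mean was 0.08 in NC 3 and between 0.16 and 0.20 in the FadA libraries.

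Of 21 tested genes of endoplasmic reticulum chaperones and their regulators, 5 rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone. CALR, the calcium-binding chaperone calreticulin, rose by 0.35 ± 0.04, XBP1, a transcription factor of the unfolded protein response, by 0.68 ± 0.09, SDF2L1 by 0.75 ± 0.13 and MANF, a secreted stress protein, by 0.35 ± 0.06. HYOU1, a chaperone of the reticulum (0.34 ± 0.07), and CRELD1, the gene that fell (-0.54 ± 0.12), were named after their values were seen. In the camera test, the Benjamini-Hochberg adjusted p was 0.0106, and the adjusted p = 0.615 with an estimated correlation. Without NC 3, 8 rose and 3 fell, without 0M 3, 2 fell, and without FadA 1, 0 fell. The list mean relative to 0M was 0.15, 0.15 and 0.18 in FadA 1, 2 and 3. It was also above 0M in NC 1 and NC 2, at 0.10 and 0.07, and stood at -0.02 in NC 3.

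Of 38 tested DNA replication genes, 13 rose, and 17 rose when adjusted over the list alone. They included RFC3, a subunit of the clamp loader (0.32 ± 0.06), RRM2 (0.56 ± 0.11) and RRM1 (0.24 ± 0.05), the subunits of ribonucleotide reductase, and MCM10, a replication initiation factor (0.26 ± 0.05). The camera adjusted p was 0.000224 with Benjamini-Hochberg adjustment, and the adjusted p = 0.522 with an estimated correlation. The number that rose was 2 without FadA 1 or FadA 2, 6 without FadA 3, 6 without 0M 1 or NC 1, 5 without 0M 2 or 0M 3, and 8 without NC 2. Without NC 3, 18 rose and 2 fell.

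Of 38 tested mitosis genes, 2 rose, and 1 rose when adjusted over the list alone. ANLN, a protein of the contractile ring, rose by 0.30 ± 0.06 and BUB1B, a checkpoint kinase, by 0.22 ± 0.07; ANLN overlaps KIAA0895 and BUB1B a read-through gene with PAK6. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.00347, and the adjusted p = 0.724 with an estimated correlation. The number that rose was 0 without FadA 2, 1 without any other library except NC 3, and 25 without NC 3. The list mean was 0.37 in NC 3 and between 0.18 and 0.24 in the FadA libraries, relative to 0M.

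Of 31 tested ribosome biogenesis genes, 9 rose, and 10 rose when adjusted over the list alone. Examples were RRP1B (0.33 ± 0.04) and NOLC1 (0.30 ± 0.05), nucleolar proteins, BYSL, an assembly factor of the small subunit (0.32 ± 0.07), and NPM1, an abundant nucleolar chaperone (0.21 ± 0.05). In the camera test, the Benjamini-Hochberg adjusted p was 0.000172, and the adjusted p = 0.615 with an estimated correlation. The number that rose was 2 without FadA 1, 3 without FadA 2, 6 without FadA 3, 5 without 0M 1, and 4 without 0M 2, 0M 3 or NC 2. Relative to 0M, the list mean was -0.26 in NC 3, and between -0.11 and 0.12 in every other library.

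Of 37 tested nuclear subunits of oxidative phosphorylation, 11 rose, and 14 rose when adjusted over the list alone. UQCRFS1, the iron-sulphur subunit of complex III, rose by 0.51 ± 0.06, and ATP5F1B and ATP5F1C, subunits of the ATP synthase, by 0.22 ± 0.04 and 0.27 ± 0.05. The camera adjusted p was 0.000125 with Benjamini-Hochberg adjustment, and the adjusted p = 0.615 with an estimated correlation. The number that rose was 4 without FadA 1 or FadA 2, 6 without FadA 3, 7 without 0M 2, 0M 3 or NC 1, and 21 without NC 3. The list mean was 0.10 in NC 3 and 0.23, 0.11 and 0.11 in FadA 1, 2 and 3, relative to 0M.

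Of 28 tested genes of glycolysis and hypoxia, 11 rose, 1 fell and 16 did not pass, with the same numbers when adjusted over the list alone. Most named members were glycolytic enzymes: PGAM1 rose by 0.57 ± 0.05, LDHA by 0.39 ± 0.05, PFKP by 0.30 ± 0.04, TPI1 by 0.43 ± 0.07, GAPDH by 0.45 ± 0.10, PKM by 0.31 ± 0.06 and ALDOA by 0.22 ± 0.04. GAPDH stood at 5743 ± 535 CPM in FadA, 4060 ± 88.4 CPM in 0M and 4356 ± 799 CPM in NC (SD, n = 3 each). MXI1, a repressor of the MYC network named after its values were seen, was the gene that fell (-0.37 ± 0.07). TPI1 and ALDOA overlap other genes. Camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.00148, and the adjusted p = 0.615 with an estimated correlation. Without NC 3, 11 rose and 8 fell, and without FadA 2, 0 fell; the list mean was -0.27 in NC 3, 0.14 and 0.31 in NC 1 and NC 2, and between 0.02 and 0.18 in the FadA libraries, relative to 0M.

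Of 7 tested metallothioneins and zinc-responsive genes, 3 rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone. SLC30A1, the zinc exporter, rose by 1.14 ± 0.20 and the metallothioneins MT1X and MT1E by 0.99 ± 0.20 and 1.08 ± 0.27. SLC39A10, a zinc importer, changed by -1.59 ± 0.38, from 97.6 ± 3.56 CPM in 0M and 91.2 ± 52.3 CPM in NC to 31.4 ± 4.92 CPM in FadA (SD, n = 3 each), and it stood at 31.1 CPM in NC 3. In the camera test, the Benjamini-Hochberg adjusted p was 0.0348, and the adjusted p = 0.615 with an estimated correlation. The list did not pass without FadA 1 or NC 3, with camera adjusted p of 0.122 and 0.344, against 0.00494 to 0.0492 without each other library. Relative to 0M, the list mean was 0.82, 0.21 and 0.16 in FadA 1, 2 and 3 and 0.20 in NC 3. SLC39A10 did not pass without FadA 1, FadA 2 or FadA 3, and 2 genes rose without FadA 1, any 0M library, NC 1 or NC 2.

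**Figure D2:**
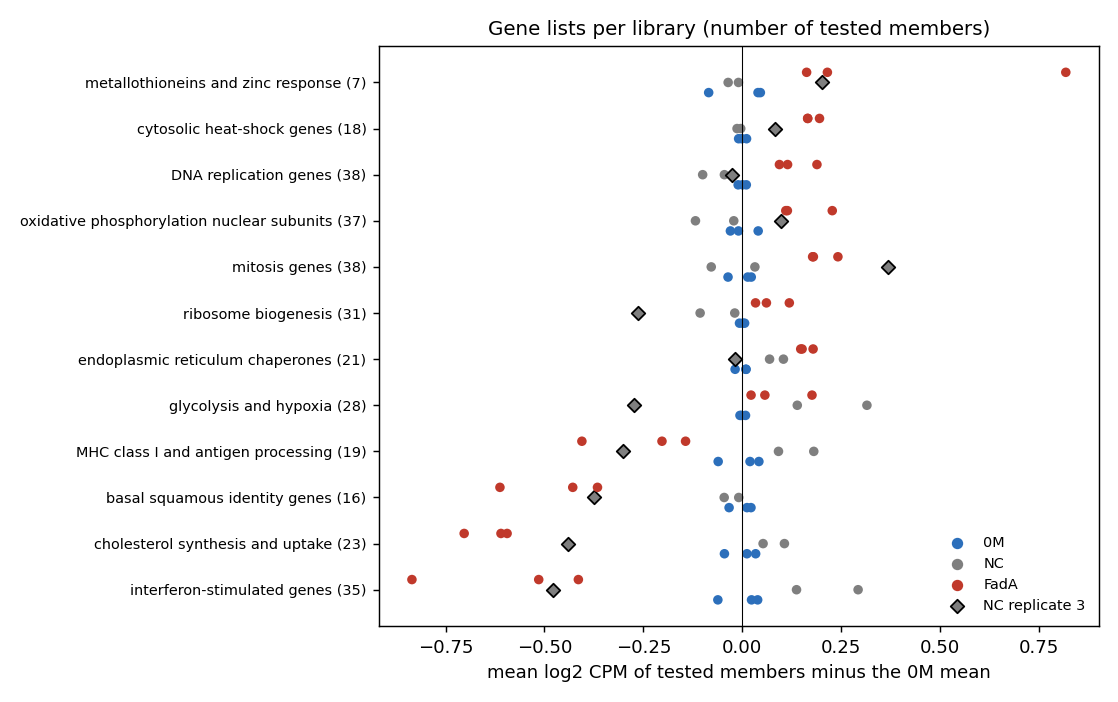
Mean log2 CPM of the tested members of the 12 lists that passed the camera test, minus the 0M mean (horizontal axis, log2 units), with each point a library coloured by group and NC 3 drawn as a diamond. For cholesterol genes the FadA libraries lie between -0.70 and -0.59, NC 3 at -0.44 and the other controls between -0.05 and 0.11.

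FadA was then compared with each control group alone, since the labels do not say which received the vehicle. Against 0M, MYH15 (log2 change 1.90 ± 0.39), IGFN1 (1.59 ± 0.30), METRNL (1.45 ± 0.27), SLC30A1 and OSBP2 had the largest named rises. TIMP3, an inhibitor of metalloproteases that overlaps SYN3 (-1.84 ± 0.43), CLEC2B, LOXL4 (-1.81 on the log2 scale), DNAH1 and LTBP2 had the largest named falls. Of 23 cholesterol genes, 18 fell, as did 8 of 16 basal squamous and 3 of 35 interferon-stimulated genes, and 6 of 18 heat-shock and 11 of 28 glycolysis and hypoxia genes rose, while 1 gene of glycolysis and hypoxia fell. When adjusted over the list alone, 19, 14 and 3 fell and 7 and 11 rose. With each library left out in turn, the falls ran from 2 to 20, 3 to 13 and 0 to 19 and the rises from 3 to 8 and 1 to 12, the highest without NC 3 and the lowest without 0M libraries. Adjusted p in the camera test with Benjamini-Hochberg adjustment was 4.43e-19, 3.88e-10, 3.2e-06, 0.00136 and 0.000362 for these lists, and the adjusted p = 0.589, 0.589, 0.614, 0.589 and 0.589 with an estimated correlation. Lists of fatty acid synthesis (0.0408), immediate-early and ERK feedback genes (0.0434) and replication-dependent histones (0.0434) passed the camera test with Benjamini-Hochberg adjustment in this comparison; the adjusted p = 0.614 with an estimated correlation for each of them.

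In total, 719 genes were higher and 724 lower in FadA than in 0M, with 25 rises and 148 falls of at least 2-fold (edgeR, Benjamini-Hochberg). The groups did not overlap for 45.3% of tested genes, where chance gives 10%. TIMP3 did not pass without any of the FadA or 0M libraries, with adjusted p between 0.0702 and 0.103 in edgeR with Benjamini-Hochberg adjustment, against 0.00084 to 0.0475 without each NC library. The number of genes, 1443, was 669, 260 and 605 without FadA 1, 2 and 3, 209, 155 and 195 without 0M 1, 2 and 3, and 3770 without NC 3, while cholesterol genes that fell numbered 7, 4, 7, 3, 2 and 4 without the FadA and 0M libraries in that order. It was 2504 with DESeq2 and 3323 when only FadA and 0M were fitted; upper-quartile factors gave 592 higher and 873 lower, and limma-trend on log2(TPM + 1) 321 higher and 688 lower.

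Against NC, SERPINB2 (1.36 on the log2 scale), OSBP2, IGFN1 (1.23 ± 0.30), MARCHF4 and TGM2 had the largest named rises. LOXL4 (-2.19 on the log2 scale), DNAH1, CLEC2B, SLITRK6 and ACP3 had the largest named falls. MYH15, SLC30A1 and MT1E did not pass against NC, with adjusted p of 0.0599, 0.0548 and 0.0725 in edgeR with Benjamini-Hochberg adjustment. Of 23 cholesterol genes, 12 fell, as did 4 of 35 interferon-stimulated and 4 of 16 basal squamous genes, and 10 of 31 ribosome biogenesis and 7 of 18 heat-shock genes rose. When adjusted over the list alone, 18, 7 and 9 fell and 14 and 9 rose. With each library left out in turn, the falls ran from 4 to 20, 1 to 22 and 2 to 13 and the rises from 2 to 13 and 5 to 9, the highest without NC 3. Adjusted p in the camera test with Benjamini-Hochberg adjustment was 1.27e-12, 5.51e-06, 0.000105, 9.71e-08 and 0.000179 for these lists, and the adjusted p = 0.629, 0.629, 0.629, 0.629 and 0.599 with an estimated correlation. Mitosis genes (adjusted p 0.0994), endoplasmic reticulum chaperones (0.0737) and metallothioneins (0.0737) did not pass the camera test with Benjamini-Hochberg adjustment in this comparison.

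In total, 866 genes were higher and 796 lower in FadA than in NC, with 14 rises and 173 falls of at least 2-fold (edgeR, Benjamini-Hochberg). The groups did not overlap for 29.6% of tested genes, where chance gives 10%. The number of genes, 1662, was 700, 374 and 928 without FadA 1, 2 and 3, 944, 887 and 995 without 0M 1, 2 and 3, and 632, 376 and 5080 without NC 1, 2 and 3, while cholesterol genes that fell numbered 4, 4, 5, 7, 6, 7, 4, 4 and 20 in that order. It was 2851 with DESeq2 and 52 when only FadA and NC were fitted; upper-quartile factors gave 650 higher and 1017 lower, and limma-trend on log2(TPM + 1) 341 higher and 803 lower.

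Genes that passed with the same sign against each control numbered 1018, of which 491 were higher and 527 lower in FadA. TFRC, TGM2, OSBP2, IGFN1, METRNL, HSP90AA1 and PGAM1 were among those that rose, and LOXL4, CLEC2B, DNAH1, INSIG1, SQLE and NGFR among those that fell. Both comparisons share the FadA libraries, and 20 simulations of unchanged groups with shared libraries gave a mean of 0 such genes. Genes in these simulations were drawn independently of each other, unlike those in the data. The simulated values therefore cannot exclude an overlap that comes from shifts of a whole library. Independent lists of the same lengths would share 44.2 higher and 40.9 lower genes. Across genes, which are not independent replicates, the log2 changes had the same sign for 84.7% against a simulated 66.5%, a Pearson correlation of 0.638 against 0.504 and a covariance of 0.317 against 0.119. The 3 FadA libraries could not be divided into groups of at least 2, so part of the excess may come from the shared libraries. The number was 444, 191 and 466 without FadA 1, 2 and 3, 193, 146 and 182 without 0M 1, 2 and 3, and 442, 330 and 3203 without NC 1, 2 and 3; it was 1821 with DESeq2. Upper-quartile factors gave 377 higher and 658 lower, and limma-trend on log2(TPM + 1) 187 higher and 488 lower.

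The control groups were compared with each other as the background of these differences. No named gene passed between NC and 0M, and the 5 with the smallest p-values failed the test with an adjusted p of 0.998 each (edgeR, Benjamini-Hochberg). These were the histone gene H2BC21 (log2 difference 0.79), EPCAM, an epithelial adhesion molecule (0.28), KRT5 (-0.26), ADM, the hormone adrenomedullin (0.50), and TNFRSF1A, a receptor for tumour necrosis factor (0.26). DESeq2 called each of these 5, with Benjamini-Hochberg adjusted p between 0.000363 and 0.0129. The features that passed in edgeR numbered 2, an assembled transcript with no gene and ENSG00000255639, while 634 genes had an unadjusted p under 0.05 and DESeq2 called 31. The number that passed was 1 without NC 1, NC 2 or NC 3. NC and 0M did not overlap for 11.3% of tested genes, where chance gives 10%.

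In the comparison of NC with 0M, 0 of the 749 tested list genes passed in edgeR over all genes, with 50 at an unadjusted p under 0.05 and 5 called by DESeq2, whereas 7 lists passed the camera test. Ribosome biogenesis (median log2 difference -0.12), basal squamous (-0.14), DNA replication (-0.05), cholesterol (-0.11) and ribosomal protein genes (-0.03) were lower, and mitosis (0.09) and histone genes (0.31) were higher. Adjusted p was 1.41e-12, 3.5e-05, 0.000185, 0.00829, 0.00829, 3.5e-05 and 0.000539 in camera with Benjamini-Hochberg adjustment, and the adjusted p = 0.743, 0.743, 0.743, 0.831, 0.893, 0.825 and 0.743 with an estimated correlation. Of these 7 calls, 4 rested on NC 3: without it, cholesterol genes had a median of 0.06 (camera adjusted p 0.00619, upward), and mitosis (-0.03), basal squamous and histone genes did not pass, with 0.103, 0.297 and 0.593 after Benjamini-Hochberg adjustment. Genes of ribosome biogenesis, DNA replication and ribosomal proteins kept their direction and passed without NC 3, with camera adjusted p of 0.00642, 0.00031 and 0.00109 (Benjamini-Hochberg). A further 9 lists passed only without NC 3, so that 13 passed: glycolysis and hypoxia (2.46e-06), MHC class I (0.000103), endoplasmic reticulum chaperones (0.00031), interferon-stimulated genes (0.00184), proteases (0.0322) and immediate-early genes (0.0335) upward, and oxidative phosphorylation (0.00413), NRF2 (0.00919) and heat-shock genes (0.0156) downward, by camera with Benjamini-Hochberg adjustment. With an estimated correlation, 0 lists passed without NC 3, and the smallest adjusted p = 0.255. When adjusted over the list alone, with all libraries, 1 basal squamous and 1 DNA replication gene was lower, 1 gene of glycolysis and hypoxia was higher and 0 genes of the other lists named here passed.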

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

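The tests of the 3 patterns weighed here were chosen only after the values they explain had been seen, while the comparisons with other choices of libraries were planned.

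NC 3 lay near the FadA libraries in many genes, and without it the genes that differed between FadA and both controls numbered 5513 in place of 2615. In 46.25% of 3323 genes called between FadA and 0M, NC 3 was nearer the 0M mean, against 1.90% to 6.92% for the FadA libraries and 93.7% and 93.0% for NC 1 and NC 2. The FadA libraries had helped to choose these genes, which lowers their own shares. This comparison therefore cannot decide whether NC 3 is a mislabelled FadA library. Other values argue against that for the features they cover. TFRC in NC 3 stood at 0.09378 of the way from the other controls to FadA. NC 3 had 0 counts of MSTRG.26317.33 and 331 of ENSG00000255639. FadA 1, 2 and 3 had 218, 253 and 280 counts of the first and 0 of the second. How reads were assigned to these features is weighed below. Removal of the trends with GC content and transcript length left the Spearman correlation across 13109 genes, between NC 3 minus the other NC libraries and FadA minus 0M, at 0.4764 from 0.482, which argues against these trends as the whole cause. A difference between the cultures or in their handling, not tested further, stays open. RNA of FadA-treated cells mixed into NC 3 would move all genes toward FadA by about the same share. TFRC moved little and MSTRG.26317.33 stayed at 0, while the cholesterol list mean was -0.4403 relative to 0M (-0.70 to -0.59 in FadA). These values argue against a mixture alone for these genes, and a mixture together with another difference stays open. NC 3 lay outside the range of the other 8 libraries in 32.73% of 8738 genes with at least 20 CPM. A mixture alone would not bring this about, but this share was within the 9.03% to 45.8% of the other libraries. This was first judged against the 22.2% that chance gives, and before that the interquartile range of positions between 0M and FadA was used (0.624 in NC 3, 0.327 and 0.409 in NC 1 and NC 2, 0.533 in FadA 1); both went against a mixture, and they were given up because FadA 1 came near NC 3 in the interquartile range and chance leaves out the spread of other libraries.

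Cholesterol genes were lower and TFRC was higher in FadA than in the controls, with 18 of 23 cholesterol genes called. After removal of the trends with GC content and length, the median log2 change of the cholesterol genes was -0.5628, from -0.5448 before, which argues against these trends. Its bootstrap SE of 0.0753 came from resampling the 23 genes as if independent and does not measure the spread between libraries. The camera adjusted p was 1.27e-15 with Benjamini-Hochberg adjustment (before the removal, the adjusted p = 0.522 with an estimated correlation). A shift between cultures that occurs without FadA stays open for the cholesterol genes, because their mean in NC 3 was -0.4403 relative to 0M, below the lowest of the other 5 controls (-0.0453) and toward the FadA libraries (-0.70 to -0.59). The same shift is argued against for TFRC, which in NC 3 stood at 0.09378 of the way from the other controls to FadA. The exposure to FadA thus remains a candidate explanation for both, as a hypothesis found and tested on the same libraries.

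MSTRG.26317.33, an assembled transcript with no gene, was counted in 0M (10.9 ± 2.47 CPM, SD, n = 3) and in FadA and at 0 in NC, at least 91.2-fold lower with a floor of 3 counts per library, with an adjusted p of 0.00167 (edgeR, Benjamini-Hochberg). ENSG00000255639 was counted only in NC (11.3 ± 0.824 CPM, n = 3), at least 95.5-fold lower in 0M with the same floor, with an adjusted p of 0.00926 (edgeR, Benjamini-Hochberg); both were named after their values were seen. That the reads of ENSG00000255639 were assigned to NDUFA9, which it overlaps, in 0M is consistent with the summed level, which differed by 1.023 CPM between NC (66.3 ± 9.50) and 0M (65.3 ± 3.64), while in FadA the sum was higher (83.9 to 97.7 CPM) and leaves this open. For MSTRG.26317.33 the sum over 26 transcripts of its locus differed by -6.207 CPM (54.6 ± 10.4 in NC, 60.8 ± 3.18 in 0M), which leaves open whether its reads went to other transcripts, since with the spread of NC neither outcome is excluded. A narrower bound of 1 SD of 0M was used first and argued against such assignment for MSTRG.26317.33; it was replaced because it left out the larger spread of NC, and no biological explanation was tested.

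All 84 choices of 3 of the 9 libraries against the other 6 were fitted. The other 6 were parted by their labels for the real choice and by a seeded draw for every other choice. For genes that differed from both controls, 1 choice, the real one, reached 2615, and the highest other, 0M 3 with NC 1 and NC 2, gave 1560. Among the other choices, only the draws for this one and for 0M 1 with NC 1 and NC 2 (140 genes) kept FadA 1, 2 and 3 together as a group. Draws that mix FadA with control libraries can widen the spread within groups and lower the count. The real choice thus had an advantage, and its rank cannot exclude chance. The libraries of the choice with 1560 genes are the 3 lowest on the first principal component. The next highest, FadA 1 with FadA 2 and NC 3, gave 1072, whereas FadA 3 with NC 3 and FadA 1 gave 1 and with NC 3 and FadA 2 gave 0. The other 6 libraries were parted differently in these choices, so the counts do not tell whether position on that component accounts for them. For genes changed the same way against each control, 1 choice reached 1018 and the highest other gave 3. Only the real choice had its comparison groups parted by label, so this count cannot exclude chance either. For the number of gene lists, 26 of 84 choices reached 12 and the highest other gave 18, so chance cannot be excluded for that number.

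For the comparisons of 3 against 3 libraries, the 10 splits are too few for a share under 0.05. FadA against 0M gave 1443 genes and the highest other split 3, and 1 of the 10 was as large. FadA against NC gave 1662 and the highest other 2, and 1 of the 10 was as large. NC against 0M gave 2 and the highest other 2, and 4 of the 10 were as large.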

How the results depend on the processing

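The removal of trends with GC content and transcript length was chosen only after the data were seen, and every other setting was planned. TFRC kept a log2 change of 0.50 to 0.58 in every setting, with adjusted p from 1.8e-41 (DESeq2) to 0.00905 (edgeR without FadA 2) after Benjamini-Hochberg adjustment, and it failed only a demand for an absolute log2 change of 1, since its change was 0.57. In what follows, counts of genes stand in the order FadA against both controls, against 0M, against NC, and the same way against each control. An adjusted p under 0.01 gave 637, 175, 203 and 107 genes, and a log2 change of at least 1 gave 259, 173, 187 and 110, because both demand more. Limma voom with sample weights gave 5899, 4827, 5332 and 3722; it weighted NC 3 at 0.138 and FadA 1 at 0.357. DESeq2 gave 2504, 2851 and 1821 in the last 3 of these comparisons and 31 for NC against 0M, and limma-trend on log2(TPM + 1) without the filter gave 1612, 702, 854 and 474, and with the filter 675 genes the same way against each control; the cause was not tested. With only the compared groups fitted, 3323 genes passed against 0M and 52 against NC; this fit against NC leaves out the closely spaced 0M libraries. The replicate number as a block gave 1651, 510, 756 and 388 genes and 1 for NC against 0M. Same-numbered libraries did not pair: the correlations of their deviations lay between -0.0859 and 0.118, 1 of 9 was above 0.1, and 2 of 9 libraries correlated best with their own number. Under the block MT1E against both controls and TIMP3 against 0M did not pass (adjusted p 0.0565 and 0.0596, edgeR, Benjamini-Hochberg); single members of lists were not read under it.

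With a library left out in turn, the counts ran from 931 to 5513, 155 to 3770, 374 to 5080 and 146 to 3203, the highest of each without NC 3, and from 1 to 3 for NC against 0M. Leaving out a library also lowers the number of samples. Camera called 12 lists, 0 with an estimated correlation, and 11 (without FadA 1) to 15 (without NC 3) with a library left out. Fry called 13, of which 8 were among the 12; mitosis (0.237), ribosome biogenesis (0.0502), metallothioneins (0.0652) and MHC class I (0.173) did not pass in it, and the lists of iron, pattern recognition, beta-catenin and p53 (0.0216 each) and fibroblast markers (0.0435) did, all adjusted by the Benjamini-Hochberg method. Of 152 values of counts, TFRC and numbers of lists, 86 stayed within the limits set for them, 65 counts moved by over 1.5 times and TFRC failed in 1. Of single genes named outside the lists, 330 values stayed on their side of the threshold, 16 fell below it and 5 rose above it. For single lists these numbers were 465, 19 and 10, and in FadA against both controls none that passed in either setting reversed, while lists that passed in neither, such as those of ferroptosis and NF-kB without NC 3, did change direction. Lists that passed camera with a rise kept the sign of their median under each scaling, but each median was lower on log2 TPM than with TMM. For DNA replication genes it was 0.068 against 0.149, and for heat-shock genes 0.116 against 0.223. At these depths, 43.3% of simulated changes of 0.5 on the log2 scale were called against both controls, so genes with changes of that size that did not pass cannot be called unchanged.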

Other observations

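The counts without single libraries given for gene lists in this part were chosen only after the data were seen, and the other tests were planned. Single members of lists that did not pass the camera test also passed in FadA against both controls. Of 14 tested genes of fatty acid synthesis, 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone. LPIN1, a phosphatidate phosphatase, changed by -1.27 ± 0.22 on the log2 scale (SE), SCD, the stearoyl desaturase, by -1.15 ± 0.29, ACSS2, an acetyl-CoA synthetase that overlaps GGT7, by -0.81 ± 0.20 and FASN, the fatty acid synthase, by -0.70 ± 0.16. ACLY, the ATP citrate lyase, also fell (-0.50 ± 0.13, named after its values were seen), and ELOVL5, an elongase of polyunsaturated chains, rose by 0.33 ± 0.04. The list did not pass the camera test, with a Benjamini-Hochberg adjusted p of 0.0823; without NC 3, whose list mean was -0.39 against -0.50 to -0.31 in the FadA libraries and 0.04 in NC 1 and in NC 2, it was 5.03e-07, and over all settings it ran from 5.03e-07 to 0.615. The number that fell was 1 without FadA 1 or FadA 2, 2 without FadA 3, 0M 2 or 0M 3, 3 without 0M 1 or NC 2, 4 without NC 1, and 7 without NC 3. Of 27 tested proteases and invasion genes, 6 fell and 3 rose, or 7 and 4 when adjusted over the list alone. PLAUR, the urokinase receptor, rose by 0.67 ± 0.09, while MMP28, a matrix metalloprotease that overlaps TAF15 (-1.35 ± 0.21), KLK6, a kallikrein protease (-0.92 ± 0.16), and the inhibitor TIMP3, which overlaps SYN3 (-1.75 ± 0.39) fell. The camera adjusted p was 0.214, and 0.0296 without NC 3, with 13 falls; over all settings it ran from 0.0296 to 0.724 (Benjamini-Hochberg). Without FadA 1 or FadA 2, 3 fell, and without any other library but NC 3, 5 fell. Proteases had a list mean of -0.55 in NC 3 and of -0.52 to -0.36 in the FadA libraries, relative to 0M.

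Of 31 tested immediate-early and ERK feedback genes, 6 fell and 3 rose, or 7 and 3 when adjusted over the list alone, with a camera adjusted p of 0.0762 (range 0.00271 to 0.639 over the settings, Benjamini-Hochberg). JUND (-0.43 ± 0.06) and PHLDA1 (-0.37 ± 0.08) fell, and FOSL1 (0.66 ± 0.15) and ETV4, which overlaps DHX8 (0.45 ± 0.10), rose; without NC 3, 15 fell, without FadA 2 or FadA 3, 1 fell, and without any other library 3 fell. The rises numbered 1 without FadA 1 or FadA 2, 2 without 0M 3 and 3 without each other library. The list mean was -0.33 in NC 3 and -0.25 to -0.12 in the FadA libraries. Of 24 tested p53 targets, TIGAR, a regulator of glycolysis, rose by 0.56 ± 0.07, and DDB2 (-0.35 ± 0.04), TP53I3, which overlaps FAM228B (-0.59 ± 0.11), MDM2, which overlaps the gene of carboxypeptidase M (-0.27 ± 0.06), and BBC3 (-0.45 ± 0.10) fell, with 3 rises and 5 falls when adjusted over the list alone; without NC 3, 6 rose and 9 fell, and without FadA 2, 2 fell. Of 19 pattern-recognition receptors and adaptors, STING1, the adaptor of cytosolic DNA sensing (-0.73 ± 0.13), CASP1 (-1.03 ± 0.19) and TRAF6 (-0.24 ± 0.05) fell and IRAK1 (0.32 ± 0.08) rose, the same numbers as when adjusted over the list alone; IRAK1 did not pass without FadA 1, FadA 2, 0M 1 or 0M 2, and without NC 3, 4 rose and 4 fell. Of 13 beta-catenin targets, RNF43, which overlaps SUPT4H1 (-0.44 ± 0.06), and MYC (-0.65 ± 0.15) fell, also when adjusted over the list alone; 3 fell without FadA 1 or NC 3 and 1 without FadA 2 or FadA 3. VLDLR, a lipoprotein receptor, rose by 0.82 ± 0.11 among 35 genes of the ATF4 and amino-acid response, and SLC38A2 (-0.64 ± 0.14) and SLC6A9, which overlaps CCDC24 (-0.36 ± 0.08), fell, the same numbers as over the list alone; without NC 3, 11 rose and 4 fell, and without FadA 2 or FadA 3, 0 fell. BBC3 and CASP1 were named after their values were seen. These 4 lists did not pass the camera test (Benjamini-Hochberg adjusted p 0.429, 0.266, 0.322 and 0.322).

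None of the lists that follow passed the camera test with all libraries. Numbers adjusted over the list alone are given after each pair of numbers over all genes. Among 16 mesenchymal genes 2 rose and 1 fell (3 and 2), with AXL at 0.60 ± 0.13. Among 22 YAP and TGF-beta targets 4 rose and 2 fell (5 and 2), with F3, the tissue factor, at 0.71 ± 0.09. Among 25 junction genes 1 rose and 2 fell (1 and 1), with the desmosomal cadherins DSG3 at -0.42 ± 0.08 and DSC3 at -0.40 ± 0.12. Among 17 squamous differentiation genes 1 rose and 2 fell (1 and 2), with FLG at 0.89 ± 0.24. Among 29 autophagy and lysosome genes 4 rose and 1 fell (4 and 1), among 26 NF-kB genes 2 rose (1), among 23 NRF2 targets 2 fell (1), among 22 ferroptosis genes 1 rose and 1 fell (1 and 0), and among 52 ribosomal protein genes 2 fell (1). The NF-kB list had a median of -0.02 and a mean of -0.04 while its camera direction was upward, with an adjusted p of 0.675. The median of the lists of iron, ferroptosis, ribosomal protein, YAP and TGF-beta, squamous differentiation and autophagy genes changed sign between scalings. With each library left out in turn, the rises in these lists ran from 0 to 3 (mesenchymal), 1 to 8 (YAP and TGF-beta), 0 to 6 (junctions), 0 to 2 (squamous differentiation), 1 to 6 (autophagy and lysosome), 1 to 3 (NF-kB), 0 to 7 (NRF2), 1 to 6 (ferroptosis) and 0 to 5 (ribosomal proteins). The falls, in the same order, ran from 0 to 6, 1 to 3, 1 to 9, 0 to 3, 0 to 4, 0 to 4, 0 to 2, 0 to 4 and 0 to 3, and the highest number of each was reached without NC 3. Without NC 3, 7 NRF2 targets rose and the camera adjusted p of that list was 0.0175 (Benjamini-Hochberg), against 0.543 with all libraries. Its mean relative to 0M was highest in NC 3, at 0.49, and stood at -0.15 and -0.10 in NC 1 and NC 2. In FadA 1, 2 and 3 it was 0.30, 0.05 and -0.08, so the FadA libraries did not share a rise over 0M. With an estimated correlation, the camera adjusted p = 0.891 with all libraries, and it was not computed without NC 3.

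Few markers of other cell types were tested. FBLN1 (-0.51 ± 0.13) and FBLN2 (-1.41 ± 0.35, named after its values were seen) fell among 6 tested fibroblast markers, CSF1R (-0.76 ± 0.17) among 7 leukocyte markers and ESAM (-1.08 ± 0.32) among 6 endothelial markers, the same numbers as when adjusted over the list alone. The fibroblast markers did not pass without FadA 1, FadA 2, 0M 1 or 0M 2, CSF1R not without FadA 1 or FadA 2, and ESAM not without any of the libraries other than NC 3. FBLN1, a matrix protein that these cells also transcribed in the controls, stood at 57.7 CPM in 0M, 57.6 CPM in NC and 40.5 CPM in FadA. Of 21 replication-dependent histone genes, 0 passed in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1; without NC 3, 8 rose, and the list mean was 0.65 in NC 3 and 0.35 to 0.41 in the FadA libraries. The 13 mitochondrially encoded genes were listed at 0 in all libraries.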
